A study of Homo sapiens with 36 samples.

How the data were processed

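The deposited data were 2 gene tables over the same 36 libraries. Per the labels, the first holds expected counts and the second holds TPM. The submitters described total RNA from 24-well plates, directional libraries made from 1000 ng of RNA, NovaSeq sequencing, read checks with FastQC 0.11.5 and quantification with Salmon 0.9.1 against GRCh38. The annotation release, the strand setting, any trimming and the step from transcripts to genes were not given in the sources used here. Of the 57665 gene identifiers, 53330 matched GENCODE 29 by identifier and version, and positions are from that release. Symbols were taken from the tables, and 1666 genes share a symbol with another gene.

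The units were checked before use. The expected counts carried decimals, with 72 to 78.9% of the cells per library at a whole number (tolerance 1e-6), so the counts were rounded before fitting. The deposited TPM had a smallest value of 0.102292 in every column, which the submitters did not explain. The match of each count column to each TPM column was also checked, as Pearson's r over 10425 genes with a mean of at least 10 CPM, each gene centred on its mean. For 33 of the 36 libraries the best match was the column of the same name. The exceptions were the 3 untreated knockout libraries, described in the report. All values in the report are therefore from the counts, and TPM served only as an alternative.

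Genes were filtered with filterByExpr by group, which left 19043 tested genes of the 44932 with any count. Counts were scaled by TMM, and CPM are relative to the TMM-scaled library size. A model with a mean for each of the 12 groups was fitted to all 36 libraries with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). P values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. The contrasts were each time against 0 h within each genotype, the knockout change minus the wild-type change at each time, and knockout against wild type at 0 h, 16 in all. Gene lists were tested with limma's camera on log2 CPM with a prior count of 2. The correlation between genes of a list was estimated from the data, and p values were adjusted over the 30 lists within a contrast. Counts of list members are given from the adjustment over all tested genes and adjusted over the list alone. With a preset correlation of 0.01, every list that passed with the estimated correlation also passed, and more lists passed.

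The groups, contrasts, tests, 30 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took 14 genes of the stress response in every comparison, the most changed genes at each time, and up to 4 members with the smallest adjusted p per list described, plus up to 3 that moved against it. The most changed genes had to pass the test, reach a mean of 1 CPM and, in the courses, show no overlap between treated and untreated libraries. The alternatives were RLE scaling, DESeq2 1.42.0, no filter, a fit of only the groups of the contrast, the replicate number as a block, a 2-fold minimum, limma on log2(TPM + 1) or log2(TPM + 0.1), a preset correlation and each library left out in turn. The same TPM fits with only TPM columns 1 and 2 of the untreated knockout were added after the data were seen.

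For genes with 3 or fewer counts over a group, the fitted fold change is not given. A ratio of summed counts per library size with an exact 95% interval is given instead, or, where a group had 0 counts, the smallest ratio allowed when that 0 is read as 3 counts. These intervals and floors cover counting error only. The fit was tested on simulated data made from these libraries, with 100 genes changed at each size. The simulated libraries were independent and had the spread that the fit estimated, so this checks the method and not the real wells. For the wild-type change at 8 h it recovered 72% of genes changed by 0.50 and 83% of those changed by 1.00 in log2, and it called 4 of 18823 unchanged genes. For the difference of the responses at 8 h it recovered 56% and 74% and called 7. The changed list was called by camera and none of the 20 unchanged lists was.

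Replicate libraries were checked for duplicates by the spread of their counts. The chi-square per degree of freedom of the 36 replicate pairs lay between 1.34 and 2.57. The labels do not say whether replicate numbers pair wells across groups. The fit was planned without a block, and the replicate number as a block was an alternative. Of 36 libraries, 20 correlated best with libraries of their own number, a share above that of unrelated numbers. No contrast had every same-number pair of libraries correlated above 0.1. Nothing was left out of the deposited tables; raw reads were not analysed here.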

Results

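Gene expression was measured by RNA sequencing in U2OS cells, a human osteosarcoma line, that carried Dmr-PERK, a fusion of the kinase domain of mouse PERK with the DmrB domain. DmrB dimerises when its small-molecule ligand, the dimerizer, is added. PERK in its dimerised form phosphorylates eIF2α, the step that starts the integrated stress response (ISR), and the phosphorylation raises translation of the transcription factor ATF4. Wild-type (WT) cells and ATF4 knockout cells were collected untreated (0 h) and after 2, 4, 8, 16 and 24 h with dimerizer, in 3 wells per genotype and time, which made 12 groups and 36 libraries. The unit of the labelled dose is not given in the sources used here. The comparisons ask which transcripts change after the dimerizer is added, and which of those changes differ without ATF4. No untreated wells at later times and no cells without Dmr-PERK were among the libraries, so hours in culture and the ligand itself are not separated from the kinase.

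Total counts per library ran from 8608783 to 16265056. Each library had counts for 26200 to 30800 genes, and 4.3 to 5.86% of its counts were mitochondrial. The expected counts deposited by the authors were fitted with edgeR, and 19043 genes were tested. Changes below are log2 fold changes ± SE from 3 libraries against 3, levels are CPM of the TMM-scaled library as mean ± SD with n = 3, and p values are adjusted. Genes and lists said to rise or fall passed at an adjusted p under 0.05. The labels do not say whether the 3 wells of a group were separate cultures, so p values measure the spread between wells. When only the groups of the contrast were fitted, with fewer samples, 45 of the list results that passed no longer did.

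In WT cells known ISR genes rose within 2 h of the dimerizer, and most of them stayed high or climbed to 24 h. CHAC1, which encodes a glutathione-degrading enzyme, rose by 2.63 ± 0.10 at 2 h, from 8.26 ± 0.856 to 50.7 ± 7.03 CPM. ASNS, the asparagine synthetase gene, rose from 61.4 ± 1.81 to 429 ± 1.41 CPM at 24 h, and SLC7A11, the cystine transporter gene, from 35 ± 2.01 to 332 ± 12.1 CPM. Genes of tRNA charging and ribosome assembly rose from 4 h. Genes of cholesterol synthesis and the extracellular matrix were lower at 24 h.

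At 2 h DDIT4, an inhibitor of mTORC1 signalling, rose by 2.22 ± 0.06, the transcription factor ATF3 by 1.93 ± 0.09, PPP1R15A, a subunit of an eIF2α phosphatase, by 1.54 ± 0.06, SESN2 by 1.52 ± 0.07 and DDIT3, which encodes CHOP, by 1.46 ± 0.07. ATF4 mRNA itself rose by 0.59 ± 0.03 at 2 h (adjusted p = 3.1e-18) and by 1.14 ± 0.03 at 24 h. At 24 h the pseudokinase gene TRIB3 had risen by 3.99 ± 0.05, SLC7A11 by 3.25 ± 0.05, CHAC1 by 3.01 ± 0.10, ASNS by 2.80 ± 0.04, SESN2 by 2.71 ± 0.06, DDIT4 by 2.15 ± 0.06, PPP1R15A by 2.15 ± 0.06, the lipoprotein receptor gene VLDLR by 1.77 ± 0.06, DDIT3 by 1.61 ± 0.07 and the stress cytokine gene GDF15 by 0.93 ± 0.09. ATF3 was then only 0.42 ± 0.10 above its start, a rise that did not pass with log2(TPM + 1) (0.32, adjusted p = 0.52). HSPA5, which encodes the ER chaperone BiP, fell by 0.47 ± 0.03 at 2 h and was 0.73 ± 0.03 above its start at 24 h. EIF2AK3, which encodes PERK, rose by 0.85 ± 0.03 at 24 h, from 676 ± 24 to 1210 ± 19.8 CPM. The tables hold no separate entry for the Dmr-PERK construct, so its reads may be part of every EIF2AK3 value here. In untreated WT replicate 1 EIF2AK3 had 650 CPM and 988 TPM, and the related kinase gene EIF2AK4 had 91.1 CPM and 30.4 TPM. TPM is scaled by transcript length, so EIF2AK3 counts were assigned to shorter transcripts than those of EIF2AK4. Whether these counts hold construct reads was not tested and stays open. EIF2AK3 was the 121st most abundant of the tested genes in untreated WT cells.

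The fixed list of ISR transcription factors and effectors rose at every time in WT cells. Of its 25 members, 21 rose and 0 fell at 2 h (22 and 0 adjusted over the list alone), with a median change of 0.75 and adjusted p = 4.4e-08 for the list. At 24 h 23 rose and 2 fell (23 and 2 adjusted over the list alone; median 1.77, adjusted p = 0.00029), with KLHL24 at −0.93 ± 0.11 and CDKN1A at −0.40 ± 0.04 against the rest. KLHL24 did not pass with log2(TPM + 1). Of 20 genes of amino acid and one-carbon synthesis, 17 rose and 3 fell at 8 h (17 and 3 adjusted over the list alone; median 1.40, adjusted p = 0.0039). CTH rose by 3.05 ± 0.06, PSAT1 by 2.35 ± 0.05 and the mitochondrial folate enzyme gene MTHFD2 by 2.17 ± 0.04, while GLUL, the glutamine synthetase gene, fell by 1.5 ± 0.16, OAT by 0.61 ± 0.04 and SHMT1 by 0.32 ± 0.07. Of 16 measured amino acid transporters, 10 rose and 2 fell at 8 h (10 and 2 adjusted over the list alone; median 0.88, adjusted p = 0.03). The members with the smallest adjusted p were SLC7A11, SLC1A5 (2.07 ± 0.04), SLC38A1 (1.98 ± 0.05) and SLC1A4 (2.13 ± 0.05). Of 20 cytosolic tRNA synthetases, 19 rose and 1 fell at 8 h (19 and 1 adjusted over the list alone; median 1.19, adjusted p = 0.0011), with GARS at 1.86 ± 0.03 and SARS at 1.74 ± 0.03, and QARS falling by 0.43 ± 0.04.

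Several other lists moved together in WT cells. Of 24 measured immediate early genes, 22 rose and 1 fell at 2 h (22 and 1 adjusted over the list alone; median 0.76, adjusted p = 0.00024), among them MYC (1.52 ± 0.04), IER2 (1.31 ± 0.04), JUN (1.63 ± 0.07) and EGR1 (1.72 ± 0.07). By 8 h 2 were above and 21 below their start (2 and 21 adjusted over the list alone; median −1.25, adjusted p = 0.031), with NR4A1 at −3.40 ± 0.09 and JUNB at −1.40 ± 0.04, while MYC stayed at 1.18 ± 0.04. All 21 measured NF-kB and cytokine genes rose at 4 h (21 and 0 adjusted over the list alone; median 1.17, adjusted p = 0.022), with RELB at 1.49 ± 0.05, TRAF1 at 2.38 ± 0.09 and CXCL8 at 2.79 ± 0.12. With log2(TPM + 1) and all TPM columns the immediate early list no longer passed at 2 h or 8 h. Its median there was 0.71 at 2 h (adjusted p = 0.17) and −1 at 8 h (adjusted p = 0.45). The NF-kB list (median 0.94, adjusted p = 0.24) no longer passed at 4 h either. Those columns include the third untreated knockout column, which did not match its counts. Changes in WT cells were not compared without that column, so its part in these losses was not tested. Of 20 cytosolic heat shock genes, 15 fell and 1 rose at 2 h (15 and 1 adjusted over the list alone; median −0.25, adjusted p = 0.00024), including HSPA8 (−0.68 ± 0.03) and HSPH1 (−0.54 ± 0.03). Of 27 measured genes of ER chaperones and ER-associated degradation, 21 fell and 1 rose at 2 h (22 and 1 adjusted over the list alone; median −0.22, adjusted p = 8.5e-05). HSP90B1 fell by 0.33 ± 0.02 and CRELD2 by 0.62 ± 0.05, and the member that rose was XBP1 (0.49 ± 0.05). At 24 h this list had 9 higher and 13 lower members (9 and 13 adjusted over the list alone; median −0.08, adjusted p = 0.81).

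All 32 ribosome biogenesis genes rose at 8 h (32 and 0 adjusted over the list alone; median 0.92, adjusted p = 0.0092), with the nucleolar helicase gene DDX21 at 1.29 ± 0.03 and DKC1 at 1.37 ± 0.04. Of 14 factors of nonsense-mediated decay, 13 rose and 0 fell at 8 h (13 and 0 adjusted over the list alone; median 0.36, adjusted p = 0.0011). Of 24 measured genes of cholesterol synthesis and uptake, 23 fell and 0 rose at 24 h (23 and 0 adjusted over the list alone; median −1.30, adjusted p = 0.00052), with STARD4 at −2.62 ± 0.06, the regulator SREBF2 at −1.28 ± 0.03 and HMGCS1 at −1.94 ± 0.05. Of 30 measured extracellular matrix genes, 25 fell and 3 rose at 24 h (25 and 3 adjusted over the list alone; median −1.10, adjusted p = 0.0066). SPARC fell by 1.60 ± 0.02, THBS1 by 3.41 ± 0.05 and the collagen gene COL1A1 by 2.15 ± 0.04, while the tenascin gene TNC rose by 2.43 ± 0.03.

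In WT cells 2328 genes were higher and 1984 lower at 2 h, 4488 and 4023 at 4 h, 5652 and 5646 at 8 h, 6419 and 6254 at 16 h, and 6292 and 6171 at 24 h. At least 2-fold changes were mostly increases at 2 h (144 higher, 34 lower) and mostly decreases at 24 h (1250 higher, 2600 lower). At 2 h 54% of the calls were increases, against 78% with limma on log2(TPM + 1). Among the most changed genes, FGF21, a secreted stress hormone, rose by 2.77 ± 0.54 at 2 h and reached 4.33 CPM on average at 24 h, from 0.1. The pseudogene CLUHP10 was higher at 2 h by a ratio of 6.56 (95% interval 1.96 to 34.3), and TNF rose by 2.46 ± 0.19. At 24 h SPRR2D and the splicing factor gene ESRP1 were nearly unread at the start and rose by ratios of 449 (95% interval 80.1 to 17800) and 251 (44.6 to 9960). BIRC7, SLN and the non-coding RNA CH507-42P11.6 had no count left at 24 h and were lower by at least 27.8-, 26.1- and 23.4-fold, and the chemokine gene CXCL14 fell by 7.39 ± 0.23.

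**Figure D1:**
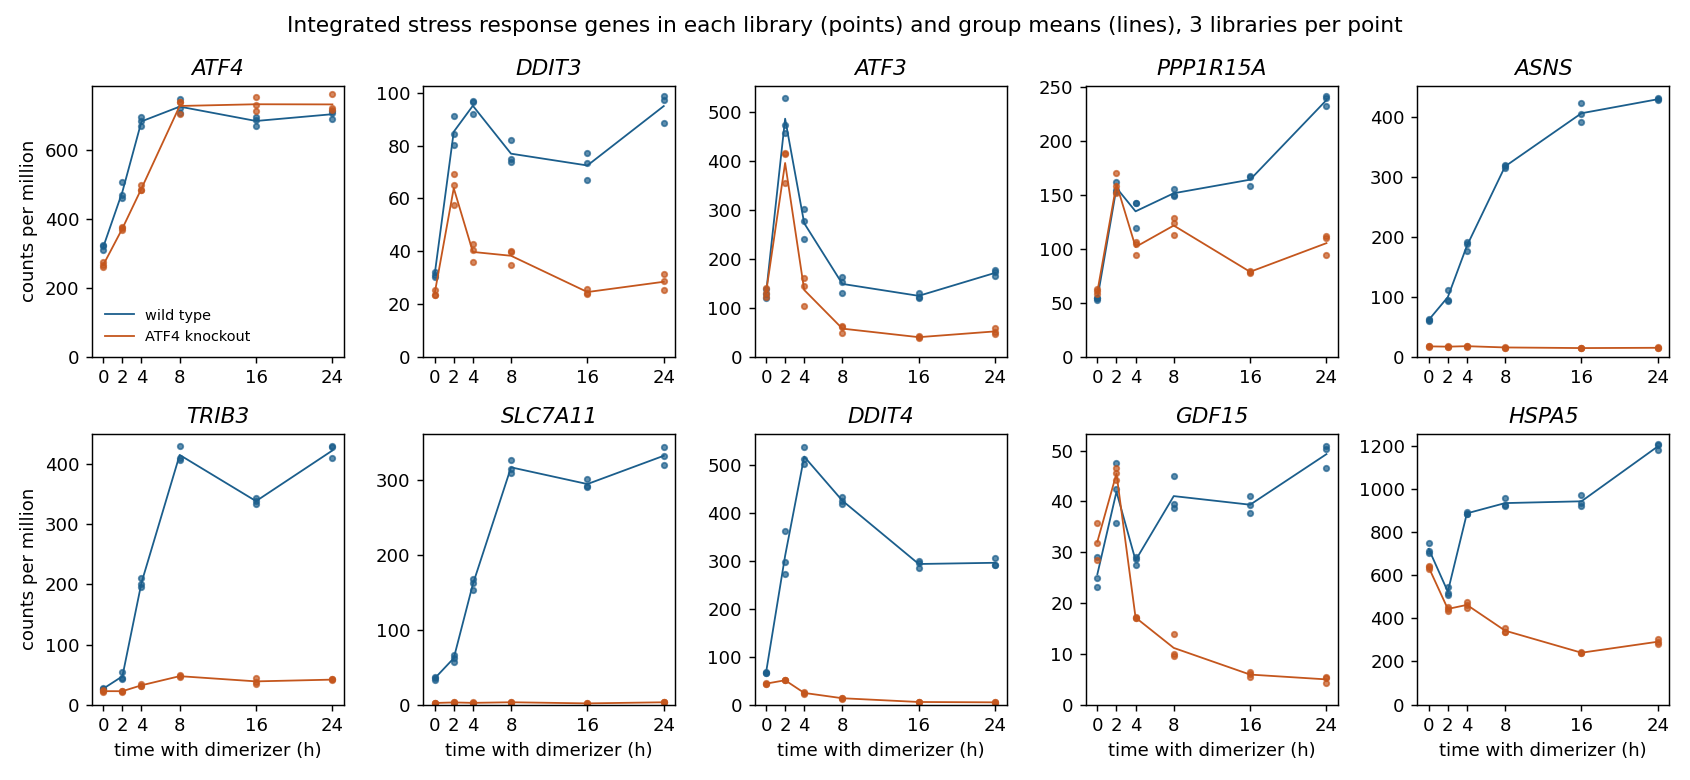
Levels in CPM of 10 genes of the stress response in each library against hours with dimerizer, for wild-type and ATF4 knockout cells; points are libraries and lines join group means. ASNS reached 429 CPM in wild-type and 14.9 CPM in knockout cells at 24 h, while ATF3 rose in both at 2 h, to 486 and 396 CPM.

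In ATF4 knockout cells DDIT3, ATF3 and PPP1R15A still rose at 2 h. Of the 25 members of the ISR list, 11 were higher, 1 was lower and 13 were not called then. GDF15 had 44 to 47 CPM per library at 2 h, against 29 to 36 CPM untreated. DDIT3 rose by 1.41 ± 0.08 at 2 h, from 24 ± 1.05 to 63.9 ± 6 CPM, ATF3 by 1.60 ± 0.09 and PPP1R15A by 1.41 ± 0.06. DDIT4 fell by 3.16 ± 0.13 at 24 h, from 43.7 ± 1.41 to 4.8 ± 0.909 CPM, GDF15 by 2.68 ± 0.13 and HSPA5 by 1.12 ± 0.03. Immediate early genes rose at 2 h and fell below their start later, NF-kB genes rose at 4 h and ribosome biogenesis genes at 8 h, and cholesterol genes fell by 24 h in these cells as well.

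ATF4 mRNA was present in the knockout cells, at 266 ± 7.47 CPM untreated against 318 ± 7.29 CPM in WT cells, and rose by 0.48 ± 0.03 at 2 h and 1.46 ± 0.03 at 24 h. Gene-level counts do not show whether an allele is disrupted. ATF3 fell below its start later, by 1.71 ± 0.12 at 16 h. That fall did not pass with log2(TPM + 1) and all TPM columns (−0.86, adjusted p = 0.064), but did with columns 1 and 2 of the untreated knockout alone. DDIT3 stood at 0.67 ± 0.08 at 8 h and 0.25 ± 0.09 at 24 h (adjusted p = 0.012). PPP1R15A stayed higher at 24 h, by 0.81 ± 0.06, and TRIB3 rose by 1.08 ± 0.07 at 8 h, from 22.4 CPM untreated. VLDLR fell by 0.51 ± 0.09 at 2 h and 1.15 ± 0.10 at 8 h. ASNS fell slightly at 24 h, by 0.22 ± 0.09 (adjusted p = 0.028), from 17.3 ± 0.868 to 14.9 ± 0.808 CPM. SLC7A11 was at 2.22 ± 0.451 CPM untreated and 3.15 ± 0.304 CPM at 24 h, a change of 0.56 ± 0.21 (adjusted p = 0.018). SESN2 rose by 0.50 ± 0.09 at 16 h and was 0.13 ± 0.10 above its start at 24 h (adjusted p = 0.23). The 24 h calls of DDIT3, ASNS and SLC7A11 ended without single libraries, which the closing section names. With log2(TPM + 1) SLC7A11 was at −0.03 (adjusted p = 0.82) with all TPM columns. It was at 0.06 (adjusted p = 0.64) with columns 1 and 2 of the untreated knockout alone. CHAC1 stayed near the limit of detection, at 0.14 ± 0.19 CPM untreated and 0.104 ± 0.109 CPM at 24 h. EIF2AK3 rose by 0.46 ± 0.03 at 24 h.

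The ISR list rose in knockout cells at 2 h, when 11 of 25 members were higher and 1 lower (13 and 1 adjusted over the list alone; median 0.22, adjusted p = 0.00025). VLDLR was the lower one. At 24 h 6 members were higher and 14 lower (6 and 14 adjusted over the list alone; median −0.25, adjusted p = 0.21), with CEBPG, a partner of ATF4 in DNA binding, at 1.90 ± 0.07 and NFIL3 at 1.14 ± 0.07 among those higher. Of the genes of amino acid and one-carbon synthesis, 12 rose and 5 fell at 24 h (12 and 5 adjusted over the list alone; median 0.32, adjusted p = 0.33). MTHFD1 rose by 1.22 ± 0.04 and PYCR1 by 1.15 ± 0.04, and PHGDH, the first enzyme gene of serine synthesis, fell by 2.85 ± 0.15. Of the amino acid transporters, 8 rose and 7 fell at 24 h (8 and 7 adjusted over the list alone; median 0.05, mean 0, and a downward test direction with adjusted p = 0.93). Of the tRNA synthetases, 18 rose and 2 fell at 16 h (18 and 2 adjusted over the list alone; median 0.70, adjusted p = 0.0098), with IARS at 1.27 ± 0.03, VARS at 1.38 ± 0.03 and FARSB at 2.13 ± 0.06, and QARS at −0.71 ± 0.04. Of the ER chaperone list, 23 members fell and 1 rose at 16 h (23 and 1 adjusted over the list alone; median −0.54, adjusted p = 0.0028), with HSPA5 at −1.40 ± 0.03, HERPUD1 at −2.56 ± 0.06 and HSP90B1 at −1.09 ± 0.02.

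Of the immediate early genes, 22 rose and 1 fell in knockout cells at 2 h (22 and 1 adjusted over the list alone; median 0.66, adjusted p = 0.00032), with MYC at 1.28 ± 0.04 and IER2 at 1.11 ± 0.04. At 24 h 3 were above and 21 below their start (3 and 21 adjusted over the list alone; median −1.59, adjusted p = 0.027). All 21 NF-kB and cytokine genes rose at 4 h (21 and 0 adjusted over the list alone; median 1.05, adjusted p = 0.027). With log2(TPM + 1) and all TPM columns neither list passed at these times, and both passed with TPM columns 1 and 2 of the untreated knockout alone. All 32 ribosome biogenesis genes rose at 8 h (32 and 0 adjusted over the list alone; median 1.15, adjusted p = 0.0096), with DDX21 at 1.36 ± 0.03 and DKC1 at 1.55 ± 0.04. Of the cholesterol genes, 22 fell and 0 rose at 24 h (22 and 0 adjusted over the list alone; median −1.53, adjusted p = 0.00055), with STARD4 at −2.79 ± 0.06 and SREBF2 at −1.41 ± 0.03. Of 29 lysosome genes, 25 fell and 3 rose at 24 h (25 and 3 adjusted over the list alone; median −0.63, adjusted p = 0.00055), with the progranulin gene GRN at −1.47 ± 0.03 and NPC2 at −1.54 ± 0.03. All 41 genes of DNA replication and S phase were higher at 24 h than at 0 h (41 and 0 adjusted over the list alone; median 0.88, adjusted p = 0.026), with CDC6 at 1.68 ± 0.06, E2F1 at 1.43 ± 0.05 and UHRF1 at 1.34 ± 0.05. That call ended with log2(TPM + 1) and all TPM columns (adjusted p = 0.16) and with only the groups of the contrast (0.23). It was kept with TPM columns 1 and 2 alone. The same list had 33 higher and 3 lower members in WT cells at 24 h (33 and 3 adjusted over the list alone; median 0.50, adjusted p = 0.15).

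In knockout cells 1875 genes were higher and 1618 lower at 2 h, 4199 and 3874 at 4 h, 5852 and 5931 at 8 h, 6289 and 6223 at 16 h, and 6176 and 6282 at 24 h. At 24 h 1158 were higher and 2525 lower by at least 2-fold. Increases were 53.7% of the calls at 2 h and 52% at 4 h, against 71.9% with log2(TPM + 1) at 2 h and 63% at 4 h when only TPM columns 1 and 2 of the untreated knockout were used. The BCL2 family gene BCL2A1 was higher by a ratio of 34.1 (95% interval 11.3 to 168) at 4 h and 169 (57.4 to 821) at 8 h, when the early-response gene NPAS4 was lower by at least 45.1-fold. At 16 h the potassium channel gene KCNA1 fell by 7.97 ± 0.27 and CXCL14 by 7.88 ± 0.20. At 24 h CXCL14 was lower by 7.42 ± 0.18. GAGE12J, a member of a gene family with near-identical copies, went from 0 counts to a level at least 5.43-fold above that floor at 2 h.

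The direct test of the difference, the knockout change minus the WT change, was negative and passed at 24 h for 23 of the 25 members of the ISR list. At 24 h the largest differences among the 14 fixed genes, apart from CHAC1 with few counts in the knockout, were DDIT4 (−5.31 ± 0.14), GDF15 (−3.61 ± 0.16), TRIB3 (−3.09 ± 0.10), ASNS (−3.02 ± 0.10), SLC7A11 (−2.69 ± 0.24), SESN2 (−2.57 ± 0.12) and VLDLR (−2.47 ± 0.11). At 2 h DDIT3, ATF3 and PPP1R15A did not differ detectably between the genotypes, while DDIT4 (−2.01 ± 0.10), SESN2 (−1.27 ± 0.12), VLDLR (−0.85 ± 0.11), TRIB3 (−0.84 ± 0.11) and ASNS (−0.74 ± 0.10) already did. TRIB3 no longer passed with log2(TPM + 1) and all TPM columns (−0.54, adjusted p = 0.3), but did with TPM columns 1 and 2 of the untreated knockout alone. Heat shock genes were on the positive side at 24 h.

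At 2 h the difference was −0.05 ± 0.11 for DDIT3 (adjusted p = 0.96), −0.33 ± 0.13 for ATF3 (adjusted p = 0.51) and −0.14 ± 0.08 for PPP1R15A (adjusted p = 0.75). All 3 had the opposite sign on the TPM scale with all columns, where the third untreated knockout column did not match its counts. Without the filter on low counts ATF3 did pass. At 24 h the 3 differed by −1.36 ± 0.11, −1.74 ± 0.15 and −1.34 ± 0.09. With log2(TPM + 1) and all TPM columns DDIT3 (−0.86, adjusted p = 0.063) and ATF3 (−0.85, adjusted p = 0.37) no longer passed at 24 h. Both passed with TPM columns 1 and 2 of the untreated knockout alone. The difference at 24 h was −1.85 ± 0.04 for HSPA5, −0.39 ± 0.04 for EIF2AK3 and 0.32 ± 0.05 for ATF4. CHAC1 differed by −3.38 ± 1.21 (adjusted p = 0.029), but by −1.82 (adjusted p = 0.63) without knockout 0 h replicate 2 and −2.78 (adjusted p = 0.077) without knockout 24 h replicate 3, with 65.8 ± 1.05 CPM in WT and 0.104 ± 0.109 CPM in knockout cells at 24 h. At 24 h ATF3, ASNS, DDIT4, GDF15, VLDLR and HSPA5 each rose in WT cells and fell in knockout cells. The ASNS fall was small (−0.22) and its call ended without single libraries.

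The ISR list had 0 members above and 7 below the WT change at 2 h (0 and 10 adjusted over the list alone; median −0.33, adjusted p = 3.4e-07) and 0 above and 23 below at 24 h (0 and 23 adjusted over the list alone; median −2.15, adjusted p = 3e-09). CEBPB, a transcription factor gene, differed by −2.15 ± 0.08 at 24 h. Of the genes of amino acid and one-carbon synthesis, 15 were below and 3 above at 24 h (15 and 4 adjusted over the list alone; median −1.12, adjusted p = 0.00028), with PHGDH at −4.11 ± 0.15, PSAT1 at −2.71 ± 0.11 and GOT1 at −1.86 ± 0.08, and MTHFD1 at 0.55 ± 0.05. Of the transporters, 12 were below and 1 above (12 and 1 adjusted over the list alone; median −0.80, adjusted p = 0.00017), with SLC7A5 at −1.74 ± 0.06 and SLC6A9 at −2.51 ± 0.12. Of the tRNA synthetases, 12 were below and 6 above (12 and 6 adjusted over the list alone; median −0.29, adjusted p = 0.025), with GARS at −1.34 ± 0.05 and SARS at −1.29 ± 0.05, and FARSB at 0.62 ± 0.08 and KARS at 0.34 ± 0.05. Of the ER chaperone list, 23 members were below and 0 above at 24 h (23 and 0 adjusted over the list alone; median −0.34, adjusted p = 2.4e-05), with HERPUD1 at −2.40 ± 0.06 and XBP1 at −1.95 ± 0.07.

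Of 22 measured NRF2 targets, 15 were below and 1 above at 24 h (15 and 1 adjusted over the list alone; median −0.73, adjusted p = 3.9e-05), with TXNRD1 at −1.30 ± 0.05, the ferritin gene FTH1 at −0.81 ± 0.04 and SRXN1 at −1.18 ± 0.06. SLC7A11 belongs to this list and to the transporters. Of the lysosome genes, 20 were below and 0 above (21 and 0 adjusted over the list alone; median −0.29, adjusted p = 0.00011), with PSAP at −0.64 ± 0.03. Of 28 autophagy genes, 13 were below and 0 above at 16 h (13 and 0 adjusted over the list alone; median −0.17, adjusted p = 0.004). Of the heat shock genes, 16 were above and 0 below at 24 h (16 and 0 adjusted over the list alone; median 0.31, adjusted p = 0.0034), with CRYAB at 0.92 ± 0.06 and HSPB1 at 0.67 ± 0.05. Of the S phase genes, 36 were above and 0 below at 24 h (36 and 0 adjusted over the list alone; median 0.45, adjusted p = 0.044), with UHRF1 at 0.90 ± 0.07 and TYMS at 0.62 ± 0.05. This list no longer passed with a replicate block (adjusted p = 0.06), with log2(TPM + 1), with only the groups of the contrast, or without WT 0 h replicate 1 (0.054), WT 24 h replicate 1 (0.052), knockout 0 h replicate 2 (0.057) or knockout 24 h replicate 3 (0.052). The 0 h levels of these S phase genes also differed between the genotypes. The lysosome median, knockout minus WT, was 0.21 at 0 h and −0.08 at 24 h. For the heat shock genes it was −0.12 at 0 h, with 10 lower and 1 higher, and 0.19 at 24 h. The lysosome and heat shock differences thus hold in part a gap present before the dimerizer. For the NRF2 targets the median went from −0.12 to −0.74.

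The number of genes with a different response was 2 above and 55 below the WT change at 2 h, 169 and 455 at 4 h, 2146 and 1331 at 8 h, 3179 and 2104 at 16 h, and 3379 and 2305 at 24 h. The 2 above at 2 h were GAGE12J and DAZAP1 (0.21 ± 0.05, adjusted p = 0.036). The call of DAZAP1 ended without any 1 of 10 of the 12 libraries, and without the filter on low counts 165 genes were called at 2 h, 27.3% of them above. At 24 h 297 genes were above and 608 below by at least 2-fold. Genes above made up 61.7%, 60.2% and 59.4% of the calls at 8, 16 and 24 h, against 44%, 48.3% and 47.1% with log2(TPM + 1). OLAH, a thioesterase gene of fatty acid synthesis, had the most negative fitted difference at 24 h (−7.64 ± 0.31), going from 1.31 to 93.2 ± 4.93 CPM in WT cells and from 2.62 to 0.857 CPM in knockout cells. ESRP1 went from 0.022 to 6.38 CPM in WT cells and stayed at 0.0431 and 0.0465 CPM in knockout cells. GABRG1, a GABA receptor subunit gene, went from 1.73 to 19.4 CPM and from 0.393 to 0.032 CPM. At 4 h DDIT4 (−3.81 ± 0.11) and SESN2 (−3.37 ± 0.13) were among the 4 lowest.

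**Figure D2:**
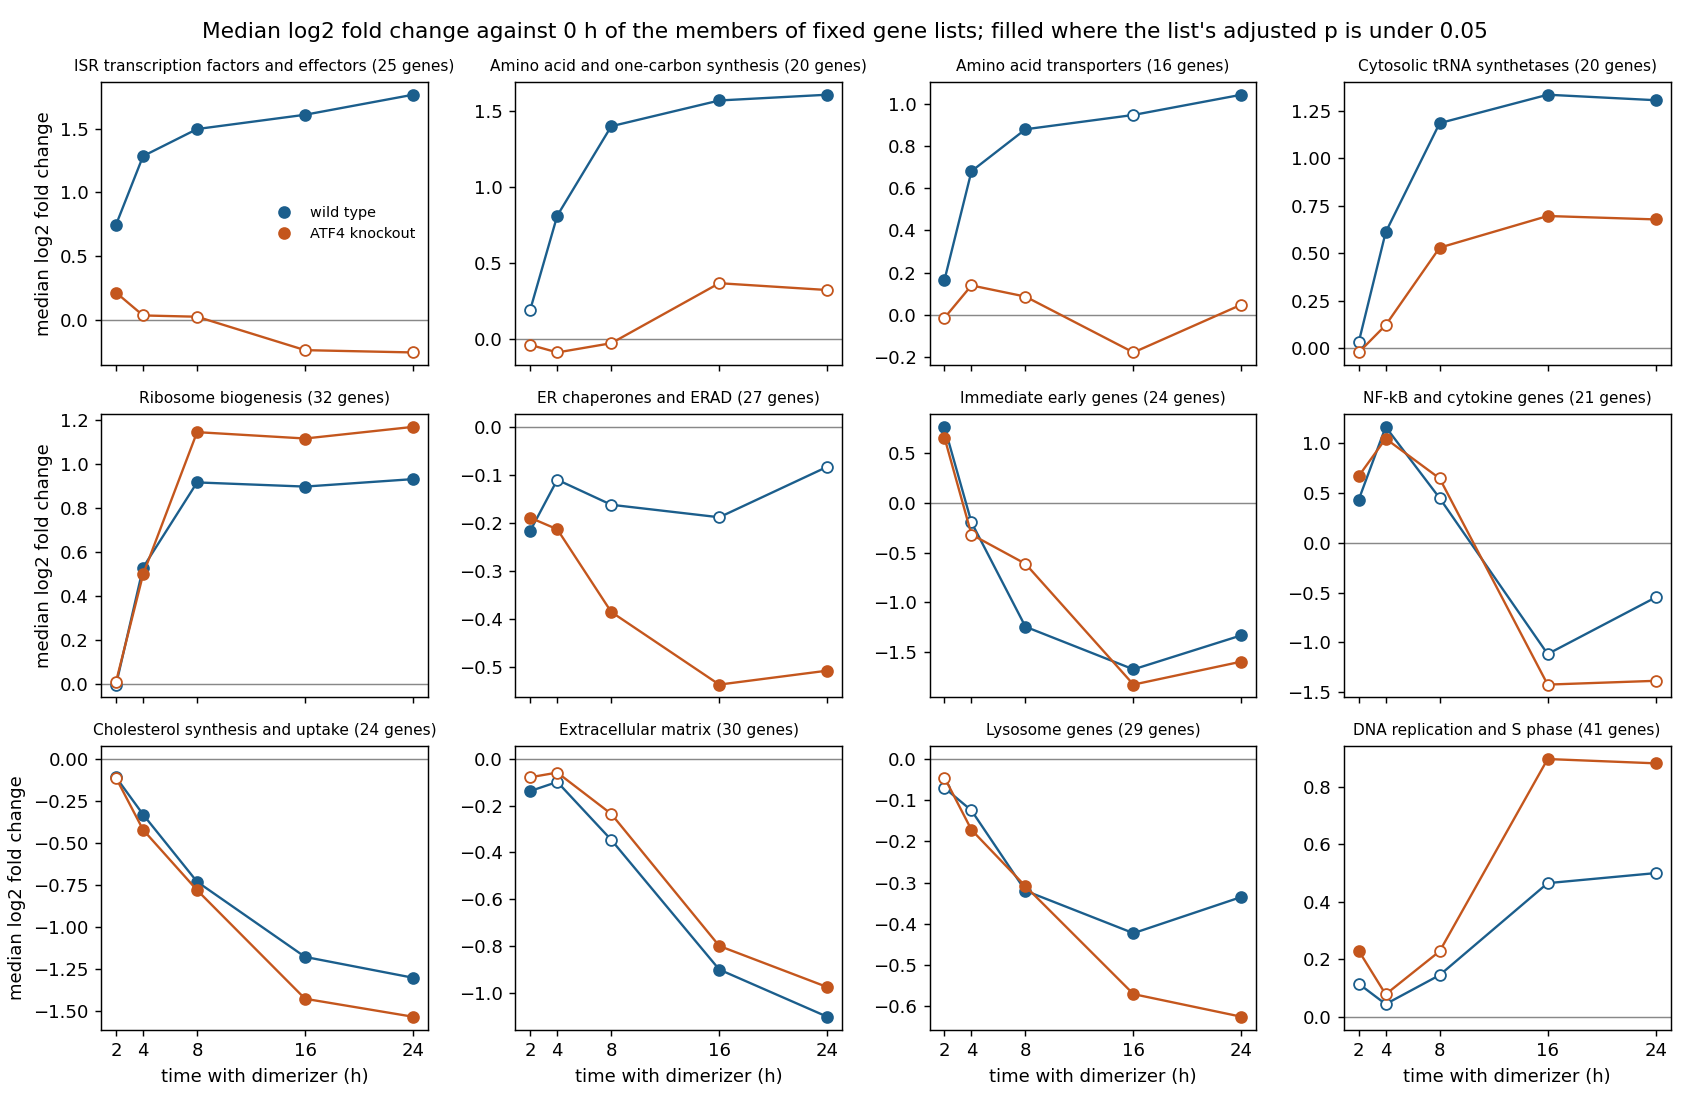
Median log2 fold change against 0 h of 12 fixed gene lists over 2 to 24 h with dimerizer, for wild-type and ATF4 knockout cells; filled points mark lists with an adjusted p under 0.05. The ISR list ended at a median of 1.77 in wild-type and −0.25 in knockout cells, and the cholesterol list at −1.30 and −1.53.

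Many genes changed in the same direction in both genotypes. Across the 19043 genes, Pearson's r between the WT and knockout changes was 0.328 at 2 h, 0.566 at 4 h, 0.685 at 8 h, 0.737 at 16 h and 0.722 at 24 h, with regression slopes of 0.351, 0.519, 0.662, 0.739 and 0.66. Genes are not independent replicates, so no p is given. With genes of at least 10 CPM alone r was 0.819 and the slope 0.757 at 2 h. Without the filter on low counts r and the slope were lower at every time. At 24 h 4892 genes were higher in both genotypes and 4808 lower in both, where independent lists would share 2041 and 2036. Another 347 genes rose in WT and fell in knockout cells, and 201 did the reverse, each with a called difference. Of the 1250 genes at least 2-fold higher in WT cells at 24 h, 479 (38.3%) had a change below and 103 a change above that in WT cells. Of the 2600 at least 2-fold lower, 640 (24.6%) had a change above and 142 a change below it. These WT calls share libraries with the test of the difference, so part of these shares rests on the same noise.

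Without dimerizer the knockout cells already had lower levels of ATF4-linked metabolic genes and higher levels of lysosome and cholesterol genes. SLC7A11 was at 2.22 ± 0.451 CPM against 35 ± 2.01 CPM in WT cells, a difference of −4.02 ± 0.12, and ASNS at 17.3 ± 0.868 against 61.4 ± 1.81 CPM (−1.83 ± 0.07). PHGDH was lower by 3.09 ± 0.06 and CBS, a gene of transsulfuration, by 2.75 ± 0.09. ATF3, with a difference of 0.03 ± 0.10 (adjusted p = 0.88), and PPP1R15A, with 0.17 ± 0.07 (adjusted p = 0.062), did not pass. PPP1R15A did pass with the replicate number as a block (0.16, adjusted p = 0.031), without the filter on low counts and with only the groups of the contrast. There was 1 knockout line, so its own history and the loss of ATF4 cannot be told apart.

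Of the 14 fixed genes, CHAC1 had 5 counts over the untreated knockout libraries against 324 in WT, and a fitted difference of −5.79 ± 0.36. SESN2 was lower by 0.61 ± 0.09, DDIT4 by 0.60 ± 0.08, DDIT3 by 0.37 ± 0.09, ATF4 by 0.26 ± 0.03, VLDLR by 0.26 ± 0.08, TRIB3 by 0.25 ± 0.08 and HSPA5 by 0.18 ± 0.03. GDF15 was higher by 0.30 ± 0.09 (adjusted p = 0.016) and EIF2AK3 by 0.33 ± 0.03. The calls of VLDLR, TRIB3 and GDF15 ended without single libraries, which the closing section names. GDF15 reversed with log2(TPM + 1) and all TPM columns (−0.23, adjusted p = 0.68). With TPM columns 1 and 2 alone neither GDF15 (0.36, adjusted p = 0.077) nor VLDLR (−0.11, adjusted p = 0.73) passed. Of the genes of amino acid and one-carbon synthesis, 19 were lower and 1 higher (19 and 1 adjusted over the list alone; median −0.70, adjusted p = 2e-05). GLUL was the higher one, by 2.06 ± 0.10. Of the tRNA synthetases, 15 were lower and 1 higher (16 and 1 adjusted over the list alone; median −0.31, adjusted p = 0.00013), with YARS at −1.55 ± 0.04 and MARS at −1.05 ± 0.04. The ISR list had 12 lower and 4 higher members (13 and 5 adjusted over the list alone; median −0.25, adjusted p = 0.011), with NUPR1 at −1.98 ± 0.10 and ADM2 at −1.62 ± 0.11. Of the transporters, 10 were lower and 4 higher (10 and 5 adjusted over the list alone; median −0.18, adjusted p = 0.014), with SLC1A5 at −0.91 ± 0.05 and SLC36A1 at 0.28 ± 0.05.

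All 41 S phase genes were lower in the untreated knockout cells (41 and 0 adjusted over the list alone; median −0.46, adjusted p = 0.0023), with MCM2 at −0.83 ± 0.05, RRM2 at −0.55 ± 0.04 and TK1 at −0.59 ± 0.05. With log2(TPM + 1) and all TPM columns this list no longer passed (median −0.24, adjusted p = 0.23). Nor did the cholesterol list at 0 h (median 0.05, adjusted p = 0.8). Both lists passed with TPM columns 1 and 2 alone. Of 35 mitosis and G2/M genes, 32 were lower and 0 higher (35 and 0 adjusted over the list alone, median −0.35, adjusted p = 0.015), with FOXM1 at −0.45 ± 0.04 and CCNB1 at −0.45 ± 0.04. With log2(TPM + 1) and all TPM columns the mitosis list reversed (median 0.14, adjusted p = 0.8). FOXM1 (−0.07, adjusted p = 0.88) no longer passed there, and CCNB1 reversed (0.02, adjusted p = 0.97). With TPM columns 1 and 2 alone this list and both genes kept direction and call. Of the lysosome genes, 19 were higher and 0 lower (22 and 0 adjusted over the list alone; median 0.21, adjusted p = 2e-05), with GRN at 0.51 ± 0.03 and TPP1 at 0.59 ± 0.04. Of the cholesterol genes, 18 were higher and 0 lower (20 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.0023), with HMGCS1 at 0.60 ± 0.04 and SREBF2 at 0.30 ± 0.03.

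At 0 h 2213 genes were higher and 2267 lower in the knockout, 344 and 133 of them by at least 2-fold. The largest increases were in PNMA5 (6.0 ± 0.16; 39.4 ± 0.897 against 0.594 ± 0.0893 CPM), the zinc transporter gene SLC30A8 (5.26 ± 0.33), TMEM108 (5.14 ± 0.55), TENM1 (4.44 ± 0.32) and HSPB7 (4.27 ± 0.20). After CHAC1, GAGE12C (−4.48 ± 0.36) and SLC7A11, the largest decreases that could be fitted were in the mitochondrial folate enzyme gene ALDH1L2 (−3.58 ± 0.15), PAPPA2 (−3.50 ± 0.36) and the peptide hormone gene SPX (−3.41 ± 0.24). RP11-603J24.9, GAGE12J and the pseudogene ASNSP1 had 0 counts in the untreated knockout and were lower by at least 37.6-, 23.6- and 8.57-fold. RP11-603J24.9 also went from 123 counts to 0 in WT cells at 4 h. In knockout cells it had 207 counts at 24 h, so its absence was not particular to the knockout. The counts of the 3 untreated knockout libraries lay close together, but their TPM columns did not match them as elsewhere. Counts of replicate 3 correlated with TPM columns 1, 2 and 3 of this group at r = 0.925, 0.965 and 0.491, against 0.908 to 0.971 for the other 33 libraries with their own columns. TPM column 3 listed ATF3 at 18.6, against 149 and 147 in columns 1 and 2, and CCNB1 at 522, against 223 and 201. ASNS at 20.4 and PNMA5 at 16.8 in column 3 were at knockout levels.

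ATF4 (ENSG00000128272.14) lies on chromosome 22 at 39519695 to 39522685 on the plus strand of GRCh38, per GENCODE 29. ASNS (ENSG00000070669.16) lies on chromosome 7 at 97852118 to 97872542, DDIT4 (ENSG00000168209.4) on chromosome 10 at 72273920 to 72276036 and SLC7A11 (ENSG00000151012.13) on chromosome 4 at 138164097 to 138242349. HSPA5 (ENSG00000044574.7) lies on chromosome 9 at 125234853 to 125241330 and EIF2AK3 (ENSG00000172071.11) on chromosome 2 at 88556741 to 88627576. All are annotated as protein-coding genes.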

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

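The tests of the S phase gap and of the TPM column, and the counts over other splits of the libraries, were chosen only after the results were seen. The test of the GAGE genes was chosen before its result, the summed level, was seen. The genes it asks about had been named by the 0 h comparison. A difference between the genotypes in the response to the dimerizer, by a direct test of that difference, was called for 57 genes at 2 h, 624 at 4 h, 3477 at 8 h, 5283 at 16 h and 5684 at 24 h. At 24 h 6 of the 14 fixed genes rose in WT and fell in knockout cells. These were DDIT4 (2.15 in WT and −3.16 in knockout, difference −5.31), GDF15 (0.93 and −2.68, difference −3.61), ASNS (2.80 and −0.22, difference −3.02), VLDLR (1.77 and −0.71, difference −2.47), HSPA5 (0.73 and −1.12, difference −1.85) and ATF3 (0.42 and −1.32, difference −1.74). With log2(TPM + 1) and all TPM columns the ATF3 rise in WT cells (0.32, adjusted p = 0.52) and its difference (−0.85, adjusted p = 0.37) no longer passed. The ASNS fall in knockout cells no longer passed without knockout 0 h replicate 2 (adjusted p = 0.1) or 3 (0.055) or 24 h replicate 3 (0.084). The medians of 3 lists had opposite signs at 24 h and the difference passed in the reported fit: the ISR list (1.77 and −0.25, median difference −2.15, adjusted p = 3e-09), the NRF2 targets (0.13 and −0.34, median difference −0.73, adjusted p = 3.9e-05) and the nuclear-encoded respiratory chain (−0.04 and 0.24, median difference 0.23, adjusted p = 0.025). Within the genotypes only the ISR rise in WT cells passed at 24 h, so the other signs are not calls. In WT cells the adjusted p was 0.37 for the NRF2 targets and 0.98 for the respiratory chain, with an upward test direction. The respiratory chain difference also ended with log2(TPM + 1) (0.29) and with only the groups of the contrast (0.059).

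The counts of genes were set against other splits of the same libraries, with only the groups of the contrast in the fit. For the difference, 100 of the 200 possible splits were drawn. The real split gave 32 genes at 2 h, 581 at 4 h, 3478 at 8 h, 4875 at 16 h and 5698 at 24 h, and 4, 7, 6, 4 and 2 splits gave as many, the real one included. That share was under 0.05 at 2, 16 and 24 h and above it at 4 and 8 h. The splits move treated libraries among untreated ones while many genes respond to the dimerizer, so they do not show what chance alone would give and decide nothing about it. In simulated data the test of the difference at 8 h called 7 of 18823 unchanged genes. Those data had independent libraries, the spread estimated by the fit and few changed genes. They therefore do not give the rate of false calls in the real libraries. The highest other splits called 1558, 10375, 13159, 6325 and 13867 genes. In the highest at 4, 8 and 24 h treated and untreated libraries traded places in 1 genotype, which adds the responses instead of subtracting them. The highest without that split were 3228, 5209 and 5679. That kind of split was not drawn at 2 or 16 h, and the source of the other high counts was not tested. For the changes against 0 h and the genotypes at 0 h, the 10 splits of 6 libraries are too few for a share under 0.05. The real counts were 3474, 8086, 11049, 12584 and 12441 in WT cells, 3039, 7794, 11644, 12367 and 12395 in knockout cells and 4177 at 0 h. The highest other count was 1 in WT and 2 in knockout cells at 2 h and 0 in the remaining 9.

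S phase genes were lower in untreated knockout than in untreated WT cells (median −0.46), a gap that had closed at 16 and 24 h (medians 0.03 and 0.02). The untreated libraries alone are excluded as the source, since 39, 39 and 35 of the 41 genes were also lower at 2, 4 and 8 h in other libraries. A shift of all genes through the scaling is excluded as well, since the list lay 0.45 below the median of all genes, a distance that 1 factor per library cannot change, and 0.26 below it with log2(TPM + 1). What stays open is a slower cell cycle in this knockout line before the dimerizer acts, either from the loss of ATF4 or from the history of the line, and neither was tested. The mitosis list, 0.34 below in the reported fit, lay 0.12 above the median of all genes with log2(TPM + 1) and all 3 columns, and 0.38 below with columns 1 and 2 alone.

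The TPM column labelled replicate 3 of the untreated knockout correlated with the counts of that label at r = 0.491, against 0.908 to 0.971 for the other 33 libraries. A factor applied in the authors' normalization is excluded, because r across genes does not change with 1 factor per column. A column that holds another library than its label may be the source, since the same counts matched TPM column 2 at 0.965. Counts of replicate 2 matched TPM columns 1 and 2 at 0.959 and 0.931, and counts of replicate 1 matched them at 0.907 and 0.91. Counts of replicates 2 and 3 thus matched best the column of the replicate before. The replicate labels of TPM columns 1 and 2 may therefore be shifted as well. No biological explanation was tested, and which library column 3 holds was not tested.

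GAGE12J and GAGE12C were lower in untreated knockout cells, GAGE12J with 0 counts. The summed level of the 11 GAGE genes was higher there, at 124 ± 4.76 CPM against 74.5 ± 3.14 CPM in WT cells, a log2 ratio of 0.73. Reads shared between near-identical copies were tested with bounds set before, a sum within 0.5 for that source and beyond 1 against it. The value lay between the bounds. GAGE12J had only 77 counts over the untreated WT libraries, so its loss could barely move the sum. The sum therefore cannot tell shared reads from a genotype difference in single copies. No biological explanation was tested.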

How the results depend on the processing

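The fits with TPM columns 1 and 2 alone of the untreated knockout were tests chosen only after the data were seen, and every other alternative was fixed before. Each alternative was set against the fit in the report, for the 16 counts of genes, the 226 gene values and 74 list results printed here and the 10 values of the responses across genes. Of 276 recomputed counts, 224 stayed within 1.5 times the reported count, among them all 16 each with RLE scaling, DESeq2 and the replicate block, and all 126 with a library left out. Counts without 1 library ran from 3442 to 4049 for WT at 2 h, from 45 to 69 for the difference at 2 h and from 3389 to 4102 at 0 h. Of 3755 recomputed gene values, 3578 kept direction and call, and of 1010 recomputed list results 914 did. RLE scaling kept all 226 genes and all 74 lists, and DESeq2 all 223 genes it tested. With the replicate block 225 of 226 genes and 73 of 74 lists did. No contrast had every same-number pair of libraries correlated above 0.1 after group means were removed. The block gave 65 genes for the difference at 2 h, made PPP1R15A pass at 0 h (0.16, adjusted p = 0.031) and ended the call of the S phase list in the difference at 24 h (adjusted p = 0.06).

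A 2-fold minimum lowered every count by construction: to 178, 985, 2616, 3835 and 3850 genes in WT cells, 149, 764, 2746, 3991 and 3683 in knockout cells, 6, 114, 430, 825 and 905 for the difference, and 477 at 0 h. With log2(TPM + 1) and log2(TPM + 0.1) fewer genes passed: 1093 and 1084 in WT cells at 2 h, 5224 and 5050 at 4 h, 1500 and 1429 in knockout cells at 2 h. For the difference they gave 23 and 19 at 2 h, 243 and 215 at 4 h, 1503 and 1419 at 8 h, 2263 and 2259 at 16 h and 2465 and 2412 at 24 h, and at 0 h 1442 and 1306. With TPM columns 1 and 2 alone the counts were 1317 and 1269 in knockout cells at 2 h and 5167 and 4908 at 4 h. For the difference they were 35 and 32, 302 and 270, 1453 and 1385, 2859 and 2838, and 3228 and 3180 at 2 to 24 h, and 2023 and 1911 at 0 h. The difference at 2 h counted 165 genes with no filter on low counts and 32 with only the groups of the contrast, which hold fewer samples. The cause of these shifts was not tested. Without the filter r across genes was 0.038, 0.123, 0.242, 0.343 and 0.321 at 2 to 24 h and the slope 0.04, 0.119, 0.235, 0.355 and 0.308. With genes of at least 10 CPM the 2 h values were 0.819 and 0.757. The levels of ATF4 per library, 299 to 859 TPM, were also lowest in untreated knockout cells.

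Values that reversed with TPM, given for log2(TPM + 1) and log2(TPM + 0.1), were DDIT3 (0.48, 0.50), ATF3 (0.54, 0.56), PPP1R15A (0.19, 0.20) and DAZAP1 (−0.06, −0.06) in the difference at 2 h. At 0 h they were ATF3 (−0.85, −0.87), PPP1R15A (−0.16, −0.16), GDF15 (−0.23, −0.24) and CCNB1 (0.02, 0.02), and in knockout cells at 24 h SLC7A11 (−0.03, −0.05) and SESN2 (−0.09, −0.09). With columns 1 and 2 alone 142 gene values kept direction and call, 5 no longer passed and none reversed, so these signs rested on the third column. Of the list results, 40 kept direction and call with columns 1 and 2 alone, 4 gained a call, and none was lost or reversed. Changes in WT cells were not compared under that setting, so the part of the third column in their lost calls was not tested. Lists that changed direction with log2(TPM + 1) were the mitosis list at 0 h (adjusted p = 0.8), the transporters in knockout cells at 24 h (0.88) and the respiratory chain in WT cells at 24 h (0.96). With log2(TPM + 1) another 17 genes and 12 lists kept their direction but no longer passed, among them KLHL24 in WT cells at 24 h (−0.08, adjusted p = 0.78), at 0 h RRM2 (−0.16), TK1 (−0.27), HMGCS1 (0.08) and SREBF2 (0.16), the S phase (adjusted p = 0.23) and cholesterol lists at 0 h (0.8), the immediate early genes at 2 h (adjusted p = 0.17 in WT and 0.053 in knockout cells) and the NF-kB genes at 4 h (0.24 and 0.14). With only the groups of the contrast, 45 lists kept their direction but no longer passed, at nearly the same medians. The transporters (0.95), the respiratory chain (0.98) and the blood markers in WT cells at 24 h (0.96) changed direction there. Lists that passed only under an alternative included the NRF2 targets in knockout cells at 24 h with log2(TPM + 1) (0.011) and with columns 1 and 2 alone (0.018), the respiratory chain there with columns 1 and 2 alone (0.019), and the S phase list in WT cells at 24 h without the filter (0.029). With a preset correlation 9 lists gained a call. Without the filter ATF3 passed in the difference at 2 h (−0.32, adjusted p = 1e-05) and PPP1R15A at 0 h (0.17, adjusted p = 0.016), and the cause was not tested.

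Single libraries decided few calls. ATF3 at 0 h ran from −0.02 to 0.08 with a library left out, and was −0.02 without WT 0 h replicate 1 or knockout 0 h replicate 2. DDIT3 in the difference at 2 h ran from −0.10 to 0.01, and was 0 without WT 2 h replicate 3 and 0.01 without knockout 2 h replicate 1. The call of ASNS in knockout cells at 24 h ended without knockout 0 h replicate 2 (−0.19) or 3 (−0.23) or 24 h replicate 3 (−0.20), of DDIT3 without 24 h replicate 3 (0.16), and of SLC7A11 without 0 h replicate 3 (0.40) or 24 h replicate 3 (0.45). CHAC1 in the difference at 24 h, near the limit of depth in the knockout, no longer passed without knockout 0 h replicate 2 (−1.82) or 24 h replicate 3 (−2.78). At 0 h GDF15 no longer passed without WT replicate 2 (0.24) or 3 (0.26) or knockout replicate 2 (0.21), TRIB3 without WT replicate 1 (−0.25) or 3 (−0.23) or knockout replicate 2 (−0.21) or 3 (−0.25), and VLDLR without WT replicate 3 (−0.17) or knockout replicate 1 (−0.22) or 3 (−0.24). DAZAP1 passed only when the library left out was knockout 0 h replicate 2 or 2 h replicate 3, and was otherwise at 0.19 to 0.22. The S phase list in the difference at 24 h did not pass without WT 0 h replicate 1 (adjusted p = 0.054), WT 24 h replicate 1 (0.052), knockout 0 h replicate 2 (0.057) or knockout 24 h replicate 3 (0.052). The mitochondrial tRNA synthetases in WT cells at 24 h did not pass without WT 0 h replicate 1 (0.053) or 2 (0.066) or 24 h replicate 1 (0.057), 2 (0.059) or 3 (0.059). The blood markers changed direction without WT 0 h replicate 1 (0.95) or 24 h replicate 1 (0.92), with adjusted p of 0.92 to 0.97 over the libraries left out, and the respiratory chain in WT cells without 0 h replicate 2 (0.99).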

Other observations

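The hypothesis on ATF4 before the dimerizer was tested as fixed before the result was seen, and no test in this part was chosen after it. Further fixed lists passed in at least 1 comparison. Of 21 snoRNA host genes, spliced RNAs that nonsense-mediated decay can remove, 17 rose and 2 fell in WT cells at 24 h (17 and 3 adjusted over the list alone; median 0.92, adjusted p = 0.017), with GAS5 at 2.13 ± 0.04 and ZFAS1 at 2.41 ± 0.05, and SNHG14 at −1.0 ± 0.06. In knockout cells 18 rose and 2 fell (18 and 2 adjusted over the list alone; median 1.07, adjusted p = 0.0093), with ZFAS1 at 2.47 ± 0.05 and GAS5 at 2.15 ± 0.05. Of 17 genes of the eIF2 kinases and the eIF2 pathway, 12 rose and 1 fell in WT cells at 24 h (12 and 1 adjusted over the list alone; median 0.40, adjusted p = 0.0075), with EIF2S2 at 1.12 ± 0.04. In knockout cells 13 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.46, adjusted p = 0.0093), with EIF2S1 at 0.85 ± 0.03 and EIF2B3 at 1.76 ± 0.07. Of 17 mitochondrial tRNA synthetases, 10 rose and 0 fell in WT cells at 24 h (10 and 0 adjusted over the list alone; median 0.24, adjusted p = 0.049) and 14 rose and 0 fell in knockout cells at 16 h (14 and 0 adjusted over the list alone; median 0.43, adjusted p = 0.0058), with NARS2 at 0.65 ± 0.05 and 0.89 ± 0.05. The WT call ended with log2(TPM + 1) (adjusted p = 0.07), with only the groups of the contrast (0.17) and without any 1 of 5 of the 6 libraries (0.053 to 0.066). Of 38 nuclear-encoded respiratory chain genes, 29 were above and 0 below the WT change at 24 h (31 and 0 adjusted over the list alone; median 0.23, adjusted p = 0.025), with CYC1 at 0.43 ± 0.05. That call ended with log2(TPM + 1) (median 0.12, adjusted p = 0.29) and with only the groups of the contrast (0.059).

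Other lists fell or split. Of 10 measured replication-dependent histones, 9 fell and 0 rose in WT cells at 24 h (9 and 0 adjusted over the list alone; median −1.65, adjusted p = 0.011), with HIST2H2BE at −2.38 ± 0.21, and 7 fell in knockout cells (7 and 0 adjusted over the list alone; median −0.82, adjusted p = 0.12). Of 22 measured interferon-stimulated genes, 15 fell and 3 rose in WT cells at 24 h (15 and 3 adjusted over the list alone; median −0.77, adjusted p = 0.028), with SAMD9 at −1.70 ± 0.10, and 14 fell and 2 rose in knockout cells (14 and 2 adjusted over the list alone; median −0.91, adjusted p = 0.026), with IFI6 at −2.18 ± 0.10. IFIT5 rose in both, by 0.53 ± 0.07 and 0.81 ± 0.07. Of 24 measured p53 targets, 17 fell and 5 rose in WT cells at 4 h (17 and 5 adjusted over the list alone; median −0.24, adjusted p = 0.022), with GADD45A at 1.28 ± 0.05 and TNFRSF10B at 0.91 ± 0.04 among those that rose. In knockout cells 15 fell and 3 rose (17 and 3 adjusted over the list alone, median −0.25, adjusted p = 0.0084), with TP53INP1 at −1.75 ± 0.07 and BTG2 at −1.10 ± 0.06. At 2 h this list had passed in the other direction in knockout cells, with 12 higher and 1 lower (12 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.025).

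The remaining lists did not pass in the reported fit. Under alternatives the ribosomal proteins in knockout cells at 24 h passed without the filter (adjusted p = 0.047) and with log2(TPM + 1) (0.012), and the mitochondrially encoded mRNAs at 8 h without the filter (0.037 in WT and 0.039 in knockout cells) and, in knockout cells, with log2(TPM + 1) (0.046). Of 78 ribosomal protein genes, 63 were lower and 0 higher in WT cells at 2 h (71 and 0 adjusted over the list alone; median −0.11, adjusted p = 0.13). At 24 h 65 were higher and 4 lower in WT cells (65 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.27) and 70 and 1 in knockout cells (71 and 1 adjusted over the list alone; median 0.35, adjusted p = 0.13), with RPL8 at 0.59 ± 0.02 and 0.81 ± 0.02, and RPL7A at −0.61 ± 0.02 in WT cells. All 13 mitochondrially encoded mRNAs were lower at 8 h in WT cells (13 and 0 adjusted over the list alone; median −0.29, adjusted p = 0.094) and in knockout cells (13 and 0 adjusted over the list alone; median −0.33, adjusted p = 0.082). Of 30 measured genes of glycolysis and hypoxia, 14 were above and 6 below the WT change at 24 h (14 and 6 adjusted over the list alone; median 0.17, adjusted p = 0.27), with VEGFA at −1.79 ± 0.08 and LDHA at 0.85 ± 0.04. Of 10 measured epithelial markers, 6 fell and 2 rose in WT cells at 24 h (6 and 2 adjusted over the list alone; median −0.73, adjusted p = 0.25), with KRT8 at −1.43 ± 0.04. Of 6 measured blood cell markers, 1 rose and 2 fell in WT cells at 24 h (1 and 2 adjusted over the list alone; median −0.26, mean −0.20, and an upward test direction with adjusted p = 0.98), with CD68 at 2.86 ± 0.26. Of 10 measured endothelial markers, 3 rose and 2 fell (3 and 2 adjusted over the list alone; median −0.01, mean 0.09, upward with adjusted p = 0.98), with ROBO4 at 3.47 ± 0.18.

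A hypothesis was that ATF4 already drives the genes that were at least 2-fold lower in the untreated knockout. If so, more than 50% of them were predicted to rise in WT cells at 24 h, and otherwise no larger a share than of all genes. Of these 133 genes, 47 (35.3%) rose in WT cells at 24 h, against 33% of all 19043 genes and 15.7% of the 344 genes at least 2-fold higher at 0 h. In knockout cells 26.3% of the 133 genes rose, against 32.4% of all genes and 7.85% of the 344. The WT share of the 133 genes lay between the 2 bounds, so the hypothesis stays open. Both gene sets were picked on the 0 h libraries that the changes at 24 h are measured against. The shares of these sets therefore rest in part on the same noise. For the 133 genes that noise would lower the WT share and raise the knockout share.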
